A study of Arabidopsis thaliana with 2 samples.

How the data were processed

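Single-cell RNA sequencing was done on protoplasts of Arabidopsis thaliana Col-0 callus. Leaves were cut from young seedlings and kept on callus-inducing medium, and calli were taken after 7 and 12 days. Each time point had 1 library, made with 10x Chromium 3′ v3.1 chemistry. The deposited matrices hold raw UMI counts per gene and cell barcode, with no normalization, per the file headers. They came from Cell Ranger 7.0.0 and genome build TAIR10, as the submitters' processing notes state. The annotation release and the cell-calling settings are not given in the sources used here. The reads were not used here.

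The feature list held 37144 genes, of which 36957 were nuclear, 133 plastid and 54 mitochondrial. All 36957 nuclear loci matched a locus of the reference annotation by identifier, and 10830 of these had a symbol there. Genome coordinates are not given, because the reference at hand was TAIR10.1. Cells were kept with at least 500 detected nuclear genes and at most 5% of UMIs from mitochondrial genes. Doublets were scored per library with scrublet, run in scanpy, at an expected rate of 0.8% per 1000 barcodes. Its automatic threshold marked 0.0142% of the 7-day and 0.00779% of the 12-day barcodes. Since this was under the set limit of 0.5%, the top-scoring expected share was removed instead, 2218 barcodes (15.7%) at 7 days and 1378 (10.7%) at 12 days. The removed barcodes had medians of 2878 and 8727.5 nuclear UMIs, close to those of the kept cells, so these calls rest on the score ranking alone. Before removal, the barcodes held 131% of the nuclear UMIs of kept cells at 7 days and 114% at 12 days. The removal thus took more UMIs at 7 days and included deep barcodes there.

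Counts of kept cells were summed per library and scaled to CPM, with the nuclear UMIs of the library as the total. Ratios are 12-day over 7-day values on the log2 scale. Their 95% intervals are exact conditional binomial intervals, and shares of cells have exact Clopper-Pearson intervals. Both cover counting error only. Where a count was 0 in one library, 0.5 was added to both counts. A share of 0 is given with the upper limit that 3 counts would set. With 1 library per time point there was no replicate, so no test was run and no p-value is given. Genes were compared where one library or the other had at least 10 CPM, and were counted as higher or lower at a ratio of at least 2-fold.

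Gene lists numbered 32, of which 14 were cell type markers and 18 were pathways or regulators. They had 334 entries at 314 loci, and 1 locus was left out because the reference pairs it with another symbol (PEAR1). The mesophyll and photosynthesis lists had the same members and are counted once. The marker lists were protoderm and epidermis, stomatal lineage, mesophyll, root hair, root cap, endodermis, quiescent centre and root stem cell niche, procambium and cambium, pericycle, companion cell, sieve element, xylem, S phase, and G2 and M phase. The others covered pluripotency, shoot meristem and embryo regulators, wound-induced reprogramming factors, auxin and cytokinin response, photosynthesis, ribosomal proteins, expansins, heat shock proteins, jasmonate, hypoxia, pathogen defence, senescence, suberin, flavonoids, glucosinolates and nitrate. A member counted as measured with at least 5 CPM in one library or the other, and as higher or lower at 1.5-fold. Each list's median was placed among 10000 random lists of the same size, drawn within 20 bins of mean expression. The median's interval came from 400 Poisson redraws of the counts.

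Both libraries were clustered together on 2000 highly variable nuclear genes, chosen within each library after genes of the pathway and regulator lists and genes seen in fewer than 10 cells were left out. Log-normalized values were centred and scaled within each library. Next came 30 principal components, 15 neighbours and Leiden clustering at resolution 0.8 with random seed 1. This gave 14 clusters in 13 classes. A cluster was named after a marker list where at least 3 of the list's genes were at least 2-fold higher in it than in other cells and its 10 leading genes did not favour another list. The names were given after these counts were seen. Clusters 5 and 8 had markers of several lists and cluster 4 was made of shallow cells, so these kept a number. Leading genes had the highest fold over all other kept cells among genes with at least 50 CPM in the cluster. Levels were compared within the 8 classes with at least 200 cells in each library.

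For shares of cells with a transcript, each cell was thinned to 2000 nuclear UMIs and shallower cells were left out. A cell counted for S phase, or for G2 and M phase, with UMIs of at least 2 genes of that list. A regulator needed 1 UMI.

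Named genes followed a rule. Over all kept cells these were the 12 with the highest and the 12 with the lowest ratio, among genes at 10 CPM or more with a UMI in at least 1% of the cells of the library where they were higher. Per list they were up to 4 members with the largest absolute ratio. All pluripotency regulators were taken, with 5 genes per direction within each class and 10 leading genes per cluster. The filters, lists, comparisons, alternatives and this rule were fixed before the data were examined. Genes named outside the rule are said to be so where they appear.

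The ratio and its interval were tested on simulated data for the all-cell comparison only, with counts redrawn from the pooled proportions and 9576 genes compared, so that the draws held counting error only. All 100 genes set to 2.83-fold and all 100 set to 4-fold were called (100%), 0% of the unchanged genes were called, and 95.3% of 2000 intervals held the true value.

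Alternatives covered the barcodes kept (all deposited, doublets kept in, a stricter filter of 1000 genes and 2% mitochondrial UMIs), scaling (organelle genes included, median-of-ratios size factors, the mean of each cell's CPM), CPM minimums of 1 and 50, and equal weight per class for classes of at least 30 cells. For clustering they covered no centring, resolutions 0.5 and 1.2, 3000 genes with 50 components, cell cycle genes left out, and thinning before clustering. For shares they covered no thinning, thinning to 1000 and 4000 UMIs, and 3 genes per list. Added after seeing the data were a minimum of 3000 UMIs per cell and leaving out cluster 4.

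Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.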

Results

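Protoplasts of leaf-derived Arabidopsis callus were profiled after 7 and after 12 days on callus-inducing medium, with 1 library at each time point and no replicate. The 7-day library held 19670 deposited barcodes with 158980329 UMIs, and the 12-day library 13414 barcodes with 157645231. After filtering, 11874 cells with a median of 3413 nuclear UMIs were kept at 7 days and 11465 cells with a median of 8366 at 12 days. Kept cells held 116044218 and 135897225 nuclear UMIs. All differences below are between these 2 libraries, and brackets hold 95% intervals.

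The first comparison asked which transcripts differed in level between 12-day and 7-day callus over all kept cells. Indole glucosinolate and root cap genes and 3 of 4 nitrate genes were higher in the 12-day library, while xylem genes and the aquaporin genes PIP1C, PIP2A and TIP2;2 were lower. Of 10000 genes with at least 10 CPM, 352 were at least 2-fold higher in the 12-day library, 184 were at least 2-fold lower, and 9464 lay in between. With equal weight per class the counts were 246 and 111, and 84 of the 184 lower genes stayed at least 2-fold lower. IGMT1 (AT1G21100), an indole glucosinolate O-methyltransferase, stood at 2.66 CPM at 7 days and 27.8 CPM at 12 days, a log2 ratio of 3.38 [3.21, 3.55]. AT5G03545, a phosphate starvation-induced transcript also known as IPS2, was 10.7-fold higher (4.60 and 49.3 CPM).

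Other genes with the highest ratios covered hormone perception, metal transport and coumarin synthesis. The abscisic acid receptor gene PYL6 (AT2G40330) had a log2 ratio of 3.25 [3.08, 3.42], and ZIP2 (AT5G59520), of the ZIP metal transporter family, one of 3.23. AT3G13610, which encodes the scopoletin synthesis enzyme F6'H1, stood at 10.5 and 80.6 CPM. The pseudogene AT2G06890 had the highest ratio under the naming rule, 3.46 [3.27, 3.65], from 2.11 and 23.2 CPM. MAP18 (AT5G44610, 1.47 and 14.5 CPM), and, by log2 ratio, AT5G52670 (3.11), AT1G27020 (2.98), scpl3 (AT1G73280, 2.91), AT1G11925 (2.83) and AT1G54890 (2.72) completed the 12 genes. Equal weight per class gave 2.46 for PYL6 and 2.49 for AT5G52670, and the mean of each cell's CPM gave 2.79 for AT5G03545 (3.42 in the main setting) and 3.68 for scpl3.

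Among the 12 genes with the lowest ratios, 3 were aquaporins, the channels that carry water across plant membranes. PIP1C (AT1G01620) stood at 458 CPM at 7 days and 124 CPM at 12 days, a log2 ratio of -1.89 [-1.91, -1.86]. PIP2A (AT3G53420) was 4.42-fold lower in the 12-day library, and the tonoplast aquaporin gene TIP2;2 (AT4G17340) 5.46-fold lower. AT5G04080, annotated as a cysteine-rich stress tolerance protein, was 15.6-fold lower, at 56.9 and 3.64 CPM. The peroxidase gene AT5G64100 had a log2 ratio of -2.85 [-2.95, -2.74], and the transcription factor gene BZIP9 (AT5G24800) one of -2.72. The other 6 were AT3G17580 (-2.28), AT1G24600 (-2.24), the defensin-like gene AT4G22230 (-2.09), AT1G71000 (-2.08), the carbonic anhydrase gene ACA7 (AT1G08080, -1.95) and AT4G28140 (-1.89). When each class weighed the same, PIP1C had -1.13, PIP2A -1.47 (-2.14 in the main setting), AT1G24600 -1.33 and AT4G28140 -0.82, which is under 2-fold.

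Gene lists with medians well above those of random lists came from indole glucosinolate synthesis, the root cap and nitrate use. The glucosinolate list had 2 of 12 members measured, CYP79B2 (28.6 and 124 CPM) and CYP83B1 (66.0 and 268 CPM), both acting early in indole glucosinolate synthesis. Its median log2 ratio was 2.07, above all 10000 random lists, and CYP79B2 had 2.12 [2.06, 2.17]. All 4 measured root cap members were higher in the 12-day library, with a median of 1.28 [1.17, 1.38] at percentile 99.92, and 0.69 with equal weight per class. These were the NAC transcription factor genes SMB (16.2 and 25.9 CPM), BRN1 (6.68 and 20.0 CPM) and BRN2 (1.34 and 6.26 CPM), and the cellulase gene CEL5 (2.98 and 5.87 CPM). Of 4 measured nitrate genes, 3 were higher: the nitrate transporter gene NRT1.1 (48.3 and 163 CPM) and the nitrate reductase genes NIA1 (48.2 and 120 CPM) and NIA2 (396 and 606 CPM). NIR1, for nitrite reductase, stood at 44.6 and 35.9 CPM, and the list median was 0.96 [0.94, 0.99].

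All 14 jasmonate and wound response genes were measured, 4 higher, 1 lower and 9 in between, with a median of 0.33, above the central range of random lists. LOX4 stood at 39.0 and 78.9 CPM, CYP94B3 at 615 and 989 CPM and JAZ8 at 186 and 294 CPM. JAZ7 was lower, with a log2 ratio of -0.95 [-1.06, -0.85], but had a log2 ratio of 0.47 when each class of cells weighed the same. Auxin response had 2 of 10 measured genes higher and 1 lower: GH3.2 (14.1 and 53.0 CPM) and IAA20 (3.35 and 7.93 CPM) against IAA19 (22.1 and 13.2 CPM), with a median of 0.20 (-0.07 for genes with at least 50 CPM). Cytokinin response had 2 of 7 higher and none lower, with CKX5, for a cytokinin oxidase, at 2.91 and 10.0 CPM and ARR3 at 6.73 and 13.6 CPM, and a median of 0.16 (-0.11 under the mean of each cell's CPM). Hypoxia response split, with LBD41 (75.8 and 155 CPM) and PCO1 (35.0 and 71.5 CPM) higher, SUS4 (136 and 70.8 CPM) and PDC1 (69.4 and 41.9 CPM) lower, 5 in between and a median of 0.23 (-0.22 under the mean of each cell's CPM).

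Xylem genes were lower in the 12-day library in all 6 measured cases. XCP1, for a xylem cysteine peptidase, stood at 70.3 and 19.5 CPM, the secondary wall cellulose synthase gene CESA4 at 6.85 and 2.44 CPM, CESA7 at 5.20 and 1.84 CPM, and the vessel regulator gene VND7 at 7.52 and 3.05 CPM. The list median was -1.40 [-1.49, -1.26], below all 10000 random lists, and -0.29 when each class of cells weighed the same. Most UMIs of the xylem list, 89.7% at 7 days and 85.1% at 12 days, came from 131 and 31 xylem-like cells. Of these, 106 and 5 had under 2000 UMIs. Few cells thus carried the difference in the summed list, which the counting interval does not cover. VND7 was less confined to them, at 57.3 CPM in xylem-like cells and 31.7 CPM in cluster 8, a class of 1727 cells.

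The cell division lists had medians below 0. G2 and M phase had 4 of 6 measured members lower and 2 in between, with CDC20.1 at 7.98 and 4.30 CPM, the cytokinesis gene KN at 9.50 and 5.72 CPM and a median of -0.62 [-0.72, -0.51]. For S phase, 3 of 8 were lower and 5 in between, led by MCM7 (11.1 and 6.62 CPM), MCM4 (7.06 and 4.30 CPM) and PCNA1 (9.19 and 5.67 CPM), with a median of -0.48. Equal weight per class gave -0.02 for G2 and M phase and -0.20 for S phase.

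Photosynthesis genes, which also served as mesophyll markers, were at low levels in both libraries. Of 6 measured, 4 were lower, among them RBCS1A (log2 ratio -1.23 [-1.42, -1.05]) and LHCB1.3 (14.8 and 7.28 CPM), and CA1 was higher (3.42 and 6.41 CPM). Their median was -0.65 [-0.74, -0.56] at percentile 0.51, and 0.14 with equal weight per class.

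Heat shock, ribosomal protein and wound-induced lists had low medians among random lists, with most members in between. The 8 heat shock genes had a median of -0.49 at percentile 0.16, with HSP17.6II (179 and 96.2 CPM) and HSP18.2 (77.7 and 51.5 CPM) lower and 6 in between. All 11 ribosomal protein genes were measured, with RPS18A (464 and 296 CPM) lower, 10 in between and a median of -0.37 at percentile 2.13. Of 6 measured wound-induced reprogramming factors, WOX13 (69.0 and 37.9 CPM) and ERF115 (43.3 and 25.4 CPM) were lower. WIND1 (388 and 310 CPM) and WIND2 (370 and 256 CPM) were among 4 in between, and the median was -0.43 at percentile 1.74.

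The other lists had medians inside the central range of random lists or fewer than 2 measured members. Of 6 measured quiescent centre and root stem cell niche markers, 2 were higher (NTT and PLT2), 2 lower (WOX5 and SCR) and 2 in between. The median was -0.14, and NTT had a log2 ratio of 1.02 (0.76 with equal weight per class). Procambium and cambium had MP higher (131 and 212 CPM) and SMXL5 (30.3 and 13.2 CPM) and ATHB8 (11.2 and 7.32 CPM) lower, with 4 in between and a median of -0.13 (0.28 for genes with at least 50 CPM). With equal weight per class MP had a log2 ratio of 0.55, SMXL5 -0.47 and ATHB8 -0.12, all within 1.5-fold. Companion cell markers split between the sucrose transporter gene SUC2 (8.26 and 2.24 CPM) and AHA3 (7.76 and 13.5 CPM), median -0.54 (-0.17 with equal weight per class). The log2 ratio of SUC2, -1.88, was -1.05 with equal weight per class. Sieve element had SEOB lower (5.03 and 1.42 CPM) and 2 of 3 in between, median -0.52 (-1.41 for genes with at least 1 CPM, -0.11 with equal weight per class). SEOB stood at 850 CPM in sieve-element-like cells, 37 at 7 days and 6 at 12 days, against 0.43 CPM in other cells. Its log2 ratio, -1.83, thus rests on few cells. The value of -3.07 with equal weight per class comes from other cells, since that setting left this small class out. Expansins had EXPA14 higher (4.56 and 8.29 CPM), EXPA10 lower (59.9 and 38.5 CPM) and EXPA1 (450 and 626 CPM) and EXPA4 in between, median 0.31 (-0.08 for genes with at least 50 CPM). Suberin had FAR5 higher (2.15 and 5.08 CPM) and FAR1 lower (85.8 and 45.7 CPM), and its median of 0.17 had the opposite sign in 9 of 11 alternatives, down to -0.91.

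Lists with every measured member within 1.5-fold were protoderm and epidermis (4 genes, median -0.12), senescence (5 genes, -0.18), shoot meristem regulators (CUC2 and KNAT6, 0.35), stomatal lineage (CYP86A2, -0.23) and pathogen defence (PAD3, 0.18). MYB36 was the 1 measured endodermis gene, at 18.0 and 27.5 CPM, and AGL15 the 1 measured embryo and seed regulator, at 23.8 and 15.1 CPM. No member of the root hair (7), pericycle (5) or flavonoid synthesis (8) lists reached 5 CPM in either library.

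**Figure D1:**
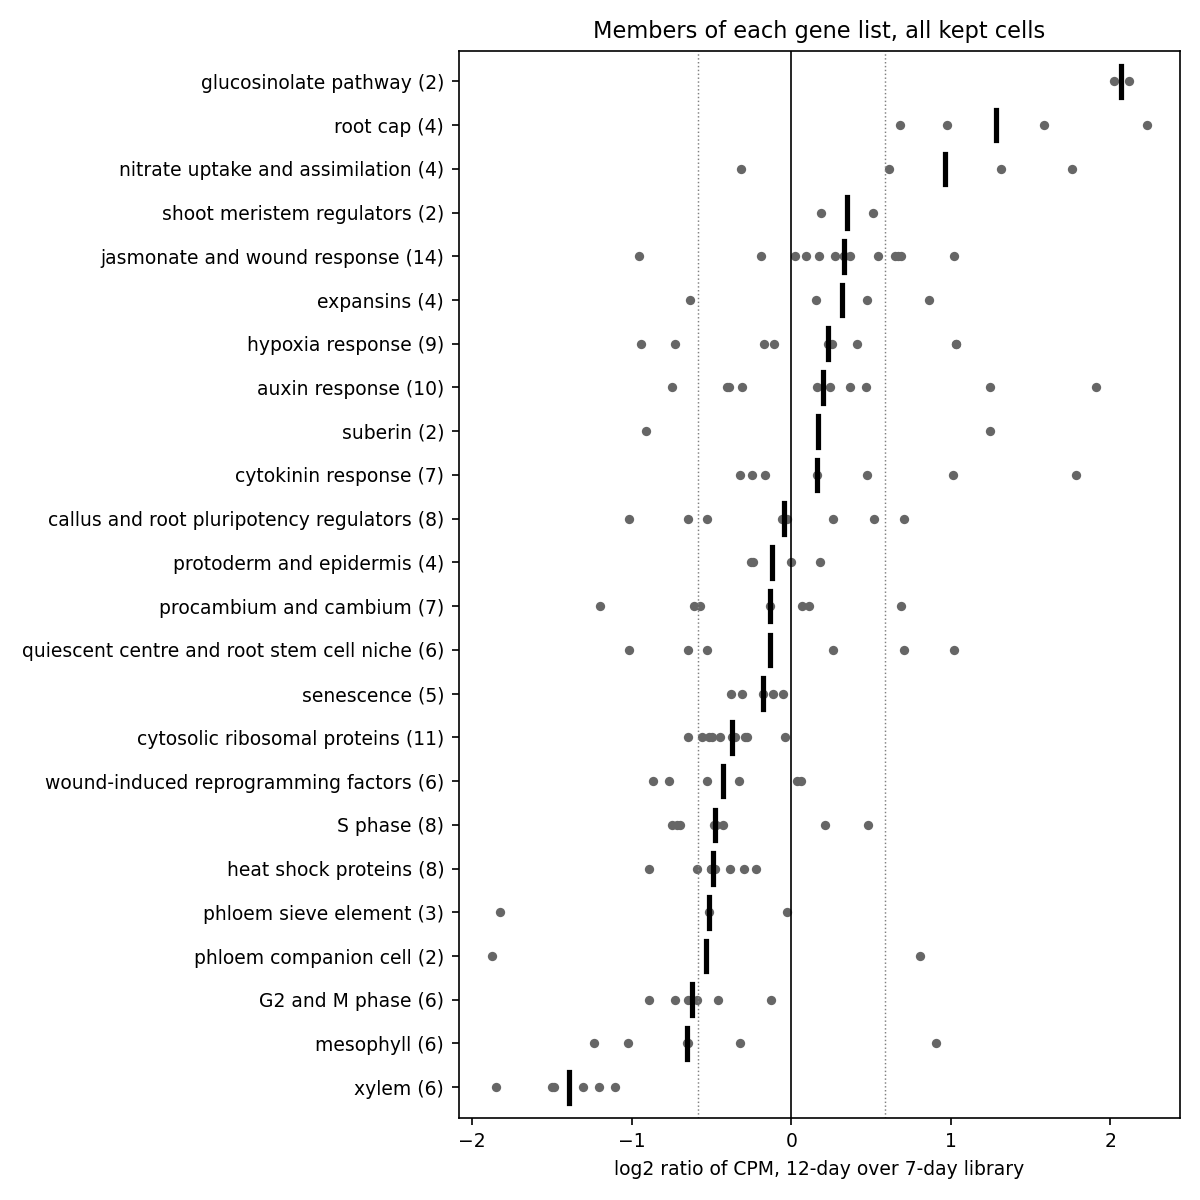
Each point is 1 measured member of a gene list, placed by its log2 ratio of CPM in the 12-day over the 7-day library over all kept cells, with a bar at the list median and no error bars. The xylem members all lie to the left of 0 (median -1.40), and the glucosinolate and root cap members to the right (2.07 and 1.28).

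The second comparison followed the regulators of callus and root pluripotency, since callus on this medium is known to take on a root-primordium-like identity. WOX5 (AT3G11260), the quiescent centre homeobox gene, was lower in the 12-day library, at 28.6 and 14.1 CPM, a log2 ratio of -1.02 [-1.10, -0.94]. PLT2 (AT1G51190) was higher, at 4.82 and 7.85 CPM (0.70 [0.56, 0.86]), and SCR (AT3G54220) lower (8.85 and 5.64 CPM). LBD16 (AT2G42430), an auxin-induced regulator of lateral root founding, had a log2 ratio of 0.52 [0.48, 0.55] from 97.5 and 140 CPM. BBM (AT5G17430) had one of -0.53 [-0.59, -0.47] from 38.1 and 26.4 CPM.

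Of the 17 regulators, 8 were measured, with 1 higher, 2 lower, 5 in between and a median of -0.04. The 1 higher, PLT2, had a log2 ratio of 0.50 with equal weight per class, which is under 1.5-fold. PLT3 (131 and 126 CPM), PLT5 (2117 and 2429 UMIs) and PLT1 (4.63 and 5.53 CPM) were in between. Below 5 CPM in both libraries were WOX11 (1.59 and 2.63 CPM), PLT7 (2.55 and 1.49 CPM), WOX7 (1.90 and 1.81 CPM), SHR (2.35 and 1.92 CPM) and LBD18 (2.25 and 2.68 CPM). WOX12 had 27 and 132 UMIs, a log2 ratio of 2.06 [1.46, 2.72], and PUCHI 27 and 37 UMIs. LBD17 had 2 and 6 UMIs (1.36 [-1.13, 4.70]) and LBD29 1 and 2 UMIs (0.77 [-3.49, 6.65]), so no difference was detectable for these 2 at this depth.

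Shares of cells with a UMI were read after thinning to 2000 UMIs, in 7217 cells at 7 days and 7955 at 12 days. WOX5 was seen in 3.03% [2.65, 3.46] of cells at 7 days and 1.58% [1.32, 1.88] at 12 days (7.55% and 4.78% unthinned). LBD16 was seen in 11.2% [10.4, 11.9] and 16.2% [15.4, 17.0] (29.2% and 42.4% unthinned), and BBM in 6.86% and 4.56% (24.8% and 21.8%). PLT2 had 0.776% and 1.52% (5.74% and 9.69%), and WOX11 0.360% and 0.729% (1.80% and 2.73%). PLT7 had 0.610% and 0.327%, or 44 and 26 cells. PLT3, in 1449 and 1474 cells, and PLT5, at 4.10% and 3.36%, had the opposite order without thinning (52.8% and 55.8%, and 19.6% and 21.5%). In all, 2 regulators had a share at least 1.5-fold higher in the 12-day library (PLT2 and WOX11) and 3 at least 1.5-fold lower (WOX5, PLT7 and BBM), among those seen in at least 20 cells of both libraries together. BBM passed in this setting only, with log2 ratios from -0.57 to -0.18 in 5 alternatives, and WOX11 had 0.29 under the stricter filter. LBD18 missed the threshold in this setting only, at 0.54 against 0.61 to 1.04 in the alternatives. Thinning to 1000 UMIs left PLT2 at 0.55 and PLT7 at -0.44.

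For the other regulators the thinned shares were 0.804% and 1.19% for PLT1 (58 and 95 cells), 0.970% and 0.842% for SCR (5.64% and 5.17% unthinned), 0.596% and 0.415% for SHR (2.76% and 2.15%), 0.416% and 0.603% for LBD18 (2.54% and 3.87%), and 0.277% and 0.264% for WOX7 (2.30% and 2.31%). WOX12 was seen in 1 cell at 7 days and 14 at 12 days (0.277% and 1.17% unthinned) and PUCHI in 3 and 3. LBD17 was seen in 0 and 2 thinned cells and LBD29 in 0 and 0. A count of 0 sets a limit of 0.0416% at 7 days and, for LBD29, 0.0377% at 12 days on cells in which the gene is detected at this depth.

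By class of cells, named in the account of cell shares, WOX5 was highest in quiescent-centre-like cells, a class named partly for it. There it was seen in 14.4% [12.2, 16.9] of cells at 7 days and 9.24% [7.38, 11.4] at 12 days (32.1% and 23.3% unthinned; 135 and 81.1 CPM). Root-cap-like cells, which should lack WOX5, gave 0.509% and 0.408%, with median depths of 10513 and 11313 UMIs against 13606 and 14225 in quiescent-centre-like cells. LBD16 in quiescent-centre-like cells was seen in 9.26% [7.45, 11.4] at 7 days and 20.0% [17.4, 22.8] at 12 days (28.6% and 46.1% unthinned), and in cluster 1 in 43.8% and 45.1%. Cluster 8 gave 0.760% and 4.27% for LBD16, cluster 7 gave 18 of 820 and 77 of 918 cells, and root-cap-like cells went the other way, 11.6% and 8.34%. No class served as background for LBD16, and RNA free in the droplets was not tested for it. PLT2 in quiescent-centre-like cells had 5.48 and 15.9 CPM, and PLT1 11.5 and 20.5 CPM.

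**Figure D2:**
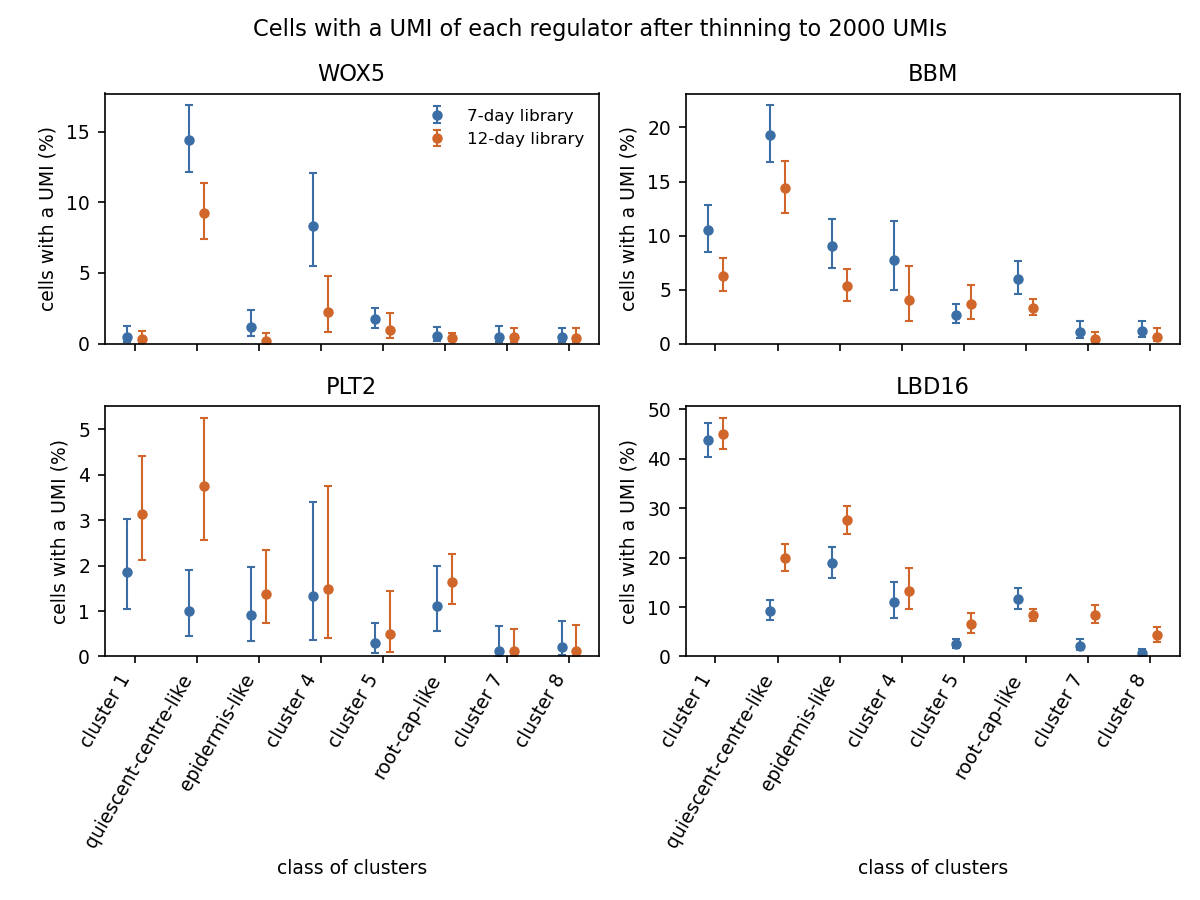
Share of cells (%) with a UMI of WOX5, BBM, PLT2 or LBD16 after thinning to 2000 UMIs, per class of clusters on the horizontal axis and per library, with exact 95% binomial intervals as bars. WOX5 is highest in quiescent-centre-like cells (14.4% and 9.24%) and LBD16 in cluster 1 (43.8% and 45.1%).

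The third comparison asked which kinds of cells made up the callus at each time point. Both libraries shared 12 of 13 classes, among them quiescent-centre-like, epidermis-like and root-cap-like cells and small groups of dividing, xylem-like and sieve-element-like cells. Root-cap-like cells were 9.11% of kept cells at 7 days and 19.4% at 12 days, a log2 ratio of 1.09 [0.98, 1.19]. They joined cluster 9, with 862 and 2169 cells, and the shallower cluster 6, which went the other way with 220 and 53 cells and medians of 2161.5 and 3151 UMIs. Cluster 5 was 18.3% at 7 days and 6.50% at 12 days (-1.49 [-1.62, -1.37]). Xylem-like cells numbered 131 and 31, and sieve-element-like cells 37 and 6 (0.312% and 0.0523%).

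The root-cap-like name rests on 3 of 7 markers (BRN1, BRN2 and CEL5), while SMB was at least 2-fold higher in cluster 1. In cluster 6, 3 of 14 epidermis markers were at least 2-fold higher too. MYB36 and AHA3, listed for endodermis and companion cells, were at least 2-fold higher in both cluster 6 and cluster 9. Of the 19 genes that define the root-cap-like class, 6 were themselves at least 2-fold apart between the libraries. In 5 of 9 alternative clusterings the class fell into clusters mostly of 1 library, with 654 and 17 cells against 152 and 1988 at resolution 1.2, 640 and 6 against 145 and 2053 under the stricter filter, and 668 and 8 against 95 and 1678 after thinning. Levels within this class therefore compare cells that these settings place in different clusters. Cluster 5 was led by ACL5 and WAT1, known from vascular tissue, and by CAB1 and LHB1B2 of the photosynthetic antenna. It had 9 of 14 procambium and 7 of 14 mesophyll markers at least 2-fold higher than in other cells, with medians of 2473 and 3239 UMIs. Most S phase markers were at least 2-fold higher in it too, among them TSO2 (73.0 against 14.5 CPM in other cells). Of the 131 xylem-like cells at 7 days, 106 had under 2000 UMIs, and of the 31 at 12 days 5 did. The log2 ratio of their share, -2.03 [-2.64, -1.45], was -0.20 after thinning to 2000 UMIs and -0.39 under the stricter filter.

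Quiescent-centre-like cells made up 7.63% [7.16, 8.12] and 7.50% [7.03, 8.00]. They had 5 of 10 list markers (WOX5, PLT1, SCR, JKD and BBM) along with 7 of 13 S phase markers. WOX5, left out of the clustering, was the leading gene, and 4 of the 10 defining genes were at least 2-fold apart between the libraries (median log2 ratio -0.90). Levels within this class therefore compare cells whose defining genes themselves differed. The log2 ratio of their share, -0.02, was -0.51 without centring. Epidermis-like cells, with 8 of 14 markers, were 6.02% [5.60, 6.46] and 8.45% [7.95, 8.98], but had a log2 ratio of -0.10 at resolution 0.5 and -0.26 with doublets kept in, so no direction is given. Cluster 1 was led by the root growth factor genes RGF2 and RGF3 and the auxin synthesis genes YUC3 and YUC7, and was 6.86% [6.41, 7.32] and 8.66% [8.15, 9.19].

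Cluster 4, at 32.2% and 31.1% of cells, was made of shallow barcodes with medians of 1014 and 1325.5 UMIs. The noncoding locus AT3G06365 alone took 16.3% of its UMIs at 7 days and 7.84% at 12 days. Cluster 7 (7.04% and 8.02%) had 8 of its 10 defining genes at least 2-fold apart between the libraries, so no direction is given. Cluster 8, led by genes such as CRF7 and HSFA3, was 7.82% [7.34, 8.31] and 6.97% [6.51, 7.45], with a log2 ratio of 0.08 under 3000 variable genes. Cluster 14 was found at 12 days only, with 107 cells, or 0.933% [0.765, 1.13], and 0 of 11874 cells at 7 days, which allows up to 0.0253%. In 5 of the 9 alternative clusterings its counterpart held 1 cell of the 7-day library. It was led by PBS3 and EDS16, both needed for salicylic acid synthesis, and by PNP-A, PUB54, NAC036, AATP1, NAC090 and NAC061.

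**Figure D3:**
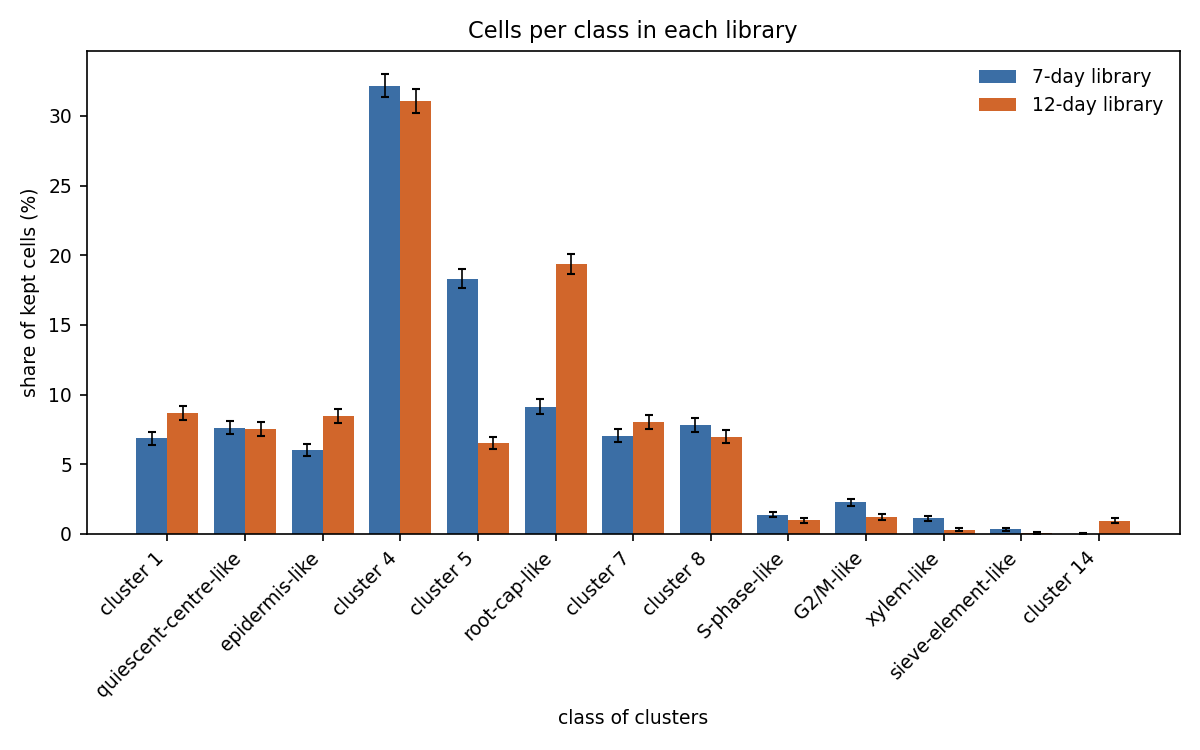
Share of kept cells (%) in each class of clusters in the 7-day and the 12-day library, with exact 95% binomial intervals as error bars. Root-cap-like cells stand at 9.11% and 19.4%, and cluster 5 at 18.3% and 6.50%.

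Dividing cells formed a smaller part of the 12-day library. G2/M-like cells, with 18 of 18 markers, numbered 267 at 7 days and 138 at 12 days, a log2 ratio of -0.90 [-1.21, -0.60] of their shares, and S-phase-like cells, with 10 of 13 markers and histone genes such as HTA6 and HTB2 in the lead, were 1.37% [1.17, 1.60] and 0.968% [0.797, 1.16]. After thinning, transcripts of at least 2 S phase genes were seen in 3.78% [3.35, 4.25] of cells at 7 days and 2.24% [1.92, 2.59] at 12 days (22.7% and 17.5% unthinned). For G2 and M phase the shares were 2.12% [1.80, 2.48] and 1.22% [0.990, 1.49] (10.9% and 7.40% unthinned). Root-cap-like cells served as background, with 0 of 982 and 3 of 2207 cells for S phase and 0.102% and 0.0906% for G2 and M phase.

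Within classes the S phase shares went both ways. Quiescent-centre-like cells had 8.15% [6.44, 10.1] at 7 days and 3.74% [2.57, 5.24] at 12 days (47.2% and 40.4% unthinned), but a log2 ratio of 0.07 after thinning to 1000 UMIs. Cluster 1 had 0.741% [0.272, 1.61] at 7 days, or 6 of 810 cells, and 5.14% [3.85, 6.70] at 12 days (17.8% and 26.4% unthinned). Its log2 ratio, 2.79 after thinning, was 0.57 without it and positive under each alternative run. G2/M-like cells had G2 and M phase transcripts in 54.1% and 48.7%.

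The last comparison asked which differences also stood within 1 class of cells. In each of the 8 classes compared, CYP79B2 and CYP83B1 were higher in the 12-day library, with class medians of the glucosinolate list from 1.51 in cluster 1 to 2.81 in epidermis-like cells. NRT1.1 was higher in all 8, most in cluster 7 (12.0 and 137 CPM) and least in root-cap-like cells (204 and 378 CPM). GH3.2 was higher in all 8 as well, from 15.8 and 29.2 CPM in cluster 5 to 3.56 and 17.1 CPM in cluster 7. RNA free in the droplets, weighed below for CYP79B2 and CYP83B1, was not tested for NRT1.1 or GH3.2. Jasmonate genes had class medians from 0.34 to 0.94, the highest in root-cap-like cells, where 11 of 13 were higher.

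Other lists differed between classes. S phase genes had a median of 1.08 in cluster 1, with 8 of 10 higher, against -0.83 in quiescent-centre-like and -0.91 in epidermis-like cells. S phase genes were not left out of the clustering, so these medians also depend on where dividing cells were placed. The S-phase-like class held 274 cells, but 92 when cell cycle genes were left out. Heat shock genes were lowest in epidermis-like cells (-0.96, 5 of 8 lower) and root-cap-like cells (-0.84, 5 of 8 lower), but had 0.18 in cluster 5 and 0.28 in cluster 8. Auxin response genes had medians of 1.00 in cluster 5 (9 of 12 higher) and 0.89 in cluster 7, and -0.41 in cluster 1. Hypoxia genes had 0.88 in cluster 1 and 0.94 in root-cap-like cells, and -0.17 in cluster 5. Nitrate genes had 1.66 in cluster 1 and 0.00 in cluster 5. List medians within classes were not run under the alternatives.

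Genes at least 2-fold apart were most numerous, on the higher side, in cluster 5 (548 higher, 166 lower of 10036), cluster 4 (513 and 136 of 10033) and cluster 7 (485 and 277 of 9773). Clusters 4 and 5 had the fewest summed UMIs of the 8 classes compared, in each library. Counting error at a given CPM is thus larger in clusters 4 and 5. How far it raised their counts of genes was not tested, so these counts do not rank the classes. Quiescent-centre-like cells had 438 higher and 151 lower of 10382, cluster 8 389 and 238 of 8959, epidermis-like cells 344 and 374 of 9655, root-cap-like cells 296 and 188 of 8021, and cluster 1 275 and 201 of 10035. With 3000 variable genes the counts in quiescent-centre-like cells were 181 and 79, and without centring those in epidermis-like cells were 197 and 190. The stricter filter gave 736 and 657 in cluster 4 and 428 higher in cluster 1, and no centring gave 390 lower in cluster 8. Cluster 4 separated by library without centring, into 3916 and 60 against 32 and 3630 cells.

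AT5G03545 was among the 5 genes with the highest ratio in 5 of the 8 classes, from 3.25 in root-cap-like to 4.54 in quiescent-centre-like cells (5.13 and 119 CPM). AT5G04080 was among the 5 lowest in 4 classes, down to -6.70 in epidermis-like cells (20.4 and 0.196 CPM; -3.73 without centring), and the peroxidase gene AT5G64100 in 3, with 155 and 8.73 CPM in epidermis-like cells (log2 ratio -4.15, -3.27 without centring). The lectin gene AT1G52060 and AT2G06890 were among the highest in 3 classes each.

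In quiescent-centre-like cells the danger peptide precursor gene PROPEP2 stood at 3.26 and 34.0 CPM (log2 ratio 3.38, but 1.33 with 3000 variable genes) and the sucrose synthase gene SUS6 at 10.5 and 2.46 CPM. Epidermis-like cells had WRKY41 at 0.753 and 17.9 CPM, IGMT1 at 1.56 and 34.7 CPM, AT3G13610 at 7.07 and 131 CPM and ERF53 at 22.6 and 1.62 CPM. Without centring the log2 ratios of WRKY41 and IGMT1 were 1.78 and 2.41 (4.57 and 4.47 in the main setting). With doublets kept in, those of AT3G13610 and ERF53 were 1.64 and -2.04 (4.22 and -3.81). In cluster 1 PYL6, CEL3 and the cytokinin response gene ARR6 were higher (3.80, 3.19 and 3.09) and HB21, PIP2A and AT4G28140 lower (-4.22, -3.10 and -3.89). CEL3 had 1.94 with 3000 variable genes, ARR6 2.25 with doublets kept in, and HB21 and AT4G28140 -2.54 and -3.10 without centring. HB21 rests on few cells, with 162 UMIs in 1.35% of cells at 7 days and 11 UMIs in 0.504% at 12 days.

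Root-cap-like cells had ZIP2 at 1.61 and 26.1 CPM and the aquaporin gene NIP2;1 at 6.10 and 60.3 CPM, while the lipid transfer protein genes LTP4 (183 and 14.9 CPM) and LTP6 (27.7 and 1.83 CPM) were lower. The log2 ratio of ZIP2, 4.02, was 3.33 after thinning, and that of LTP6, -3.92, was -3.07 with 3000 variable genes. EARLI1 (16.1 and 0.664 CPM), seen in only 1.57% and 0.810% of cells, had a log2 ratio of -4.60, but -0.12 under the stricter filter. Cluster 7 had the dirigent protein gene DIR6 at 22.4 and 337 CPM and WRKY29 at 4.84 and 71.7 CPM, against the sulfur deficiency gene LSU2 at 228 and 21.2 CPM. In cluster 8 the lignin pathway gene 4CL5 stood at 1.01 and 18.4 CPM and the malate channel gene ALMT1 at 3.86 and 41.9 CPM (log2 ratios 4.19 and 3.44, but 2.41 for 4CL5 with at least 3000 UMIs, chosen after seeing the data, and 2.32 for ALMT1 under the stricter filter). Cluster 5 had BZIP9 at 143 and 9.12 CPM, DIR1 at 52.0 and 2.35 CPM and YAB2 at 28.0 and 3.91 CPM, all lower. DIR1 had a log2 ratio of -1.72 after thinning (-4.47 in the main setting), and BZIP9 one of -2.94 with at least 3000 UMIs (-3.97). That UMI minimum gave 3.29 for DIR6 in cluster 7 (3.91). In cluster 4 LSU1 stood at 81.7 and 15.1 CPM (log2 ratio -2.44, -1.52 after thinning) and IGMT1 at 3.41 and 52.3 CPM (3.94, 3.18 after thinning).

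**Figure D4:**
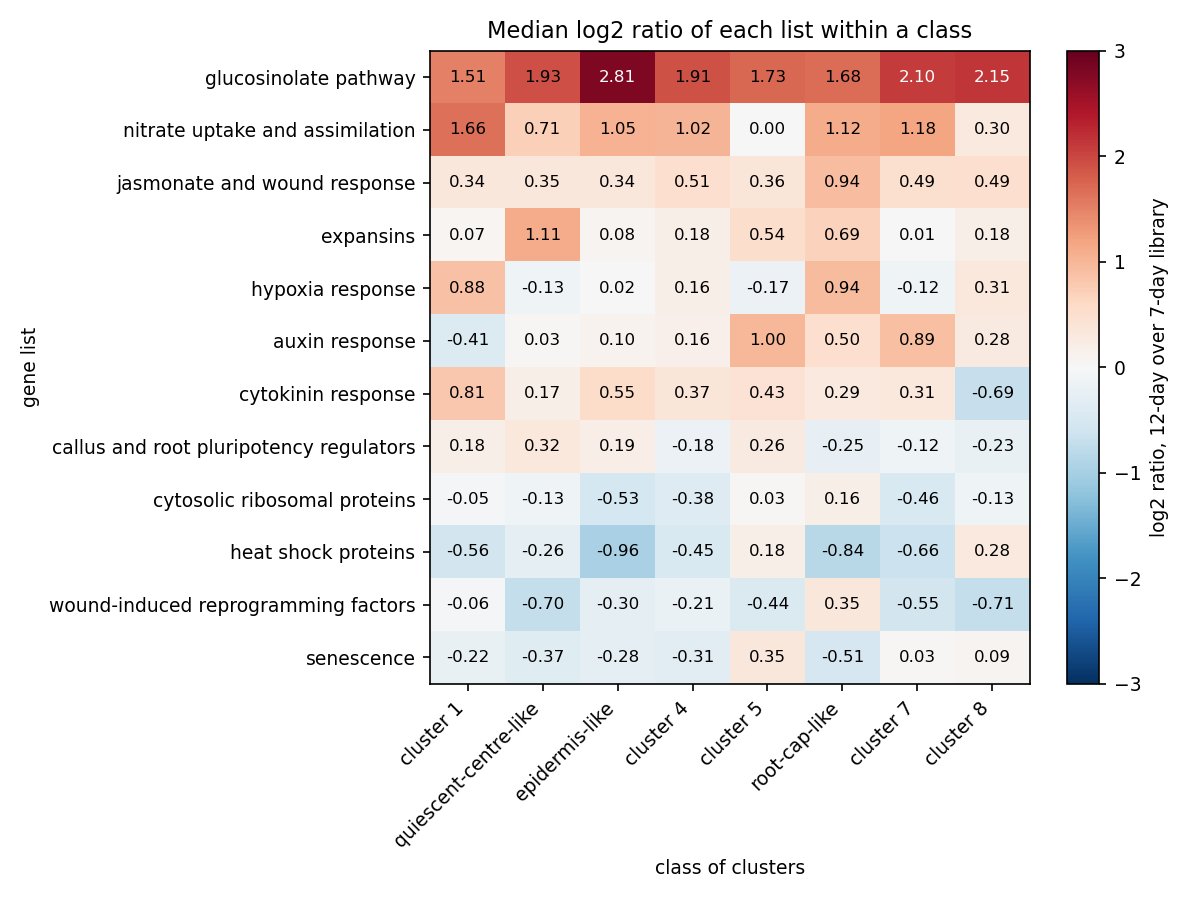
Median log2 ratio of CPM in the 12-day over the 7-day library for each gene list (vertical axis) within each of the 8 classes compared (horizontal axis), written in each cell and drawn as colour, with no error bars. The glucosinolate list is above 1.5 in every class drawn, and heat shock genes are at -0.96 in epidermis-like cells against 0.28 in cluster 8.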

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

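All tests were written after their result, or a result that foretold it, was seen, except those of the UMI share of xylem-like cells and of doublets in cluster 14. The alternative of cells with at least 3000 UMIs was also chosen after seeing the data.

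Transcripts of the organelle genomes were outside the comparisons and stood above the level that a count of 0 allows. Plastid transcripts took 0.262% of the UMIs of kept cells at 7 days and 0.195% at 12 days, and mitochondrial transcripts 0.807% and 0.592%.

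Xylem markers were lower in the 12-day library, with a median log2 ratio of -1.40. Among cells with at least 3000 UMIs the median was -1.44, so the difference also stood among deeper cells. These cells held 93.3% of the nuclear UMIs of kept cells at 7 days. The setting thus left out few UMIs and was a weak test of shallow barcodes as the source. Within xylem-like cells the median, over 14 genes rather than the 6 measured over all cells, was -0.21 [-0.40, -0.11]. That is too small for a lower level within these cells to be the whole cause. On the summed list, with a log2 ratio of -1.48, replacing only the level within these cells gave -0.49. Their summed xylem CPM was 17943 at 7 days and 12145 at 12 days. Replacing only the UMI share of xylem-like cells (0.768% and 0.385%) gave -0.85, or 57.6% of the log2 ratio of the summed list. Replacing only the level in other cells gave -0.07. No single replacement thus reached the summed difference between these libraries. No interval was computed for these parts, so how the causes divide is left open.

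CYP79B2 and CYP83B1 were higher in the 12-day library, with log2 ratios of 2.12 and 2.02. The lowest median of both genes within the 8 classes was 1.51, which argues against a different mix of cell classes. Free RNA would add like numbers of UMIs per cell, but among 4 classes of like depth the largest gain was 8.13 [6.13, 10.7] times the smallest, which argues against it as the whole cause. Among clusters 4, 5, 7 and 8, with the smallest gains of the 8 classes, the largest was 2.24 times the smallest. Classes with the smallest gains differ little in gain by selection. Their depths also differed, with medians from 1014 to 15892 UMIs at 7 days. This ratio therefore decides nothing, and free RNA cannot be told apart from other causes there. A difference between the libraries other than time cannot be told apart from time, since each time point had 1 library.

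Cluster 14, led by the salicylic acid synthesis genes PBS3 and EDS16, held 107 cells of the 12-day library and 0 of the 7-day library. When doublets were kept in, 6.90% [3.02, 13.1] of the cells of its cluster were marked as doublets. The interval holds the 10.7% marked over the 12-day library, a share fixed beforehand. These marks rest on the score ranking alone, so they cannot decide on doublets as its source. With 10 leading genes chosen among 12-day cells alone, at least 4 were seen in 0 of 7217 cells with at least 2000 UMIs at 7 days and, after thinning to 7-day depths, 53 of 7955 at 12 days. The 7-day share was thus 0% [0, 7.95] of the 12-day share (upper limits of 7.24 unthinned and 22.3 with all cells thinned to 2000 UMIs), which argues against like cells of the 7-day library placed in other clusters. A difference between the libraries other than time cannot be told apart from time with 1 library per time point.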

How the results depend on the processing

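All settings were planned except the minimum of 3000 UMIs and leaving out cluster 4, which were chosen after seeing the data. No paired analysis was possible, because both libraries have replicate number 1 and no result comes from a test. Unless said otherwise, the cause was not tested.

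All 352 genes at least 2-fold higher over all cells had ratios above 0 in each of the 11 alternatives, and all 184 lower genes ratios below 0, except 183 under the mean of each cell's CPM. Under equal weight per class only 241 of these higher and 84 of these lower genes stayed at least 2-fold apart, and under the mean of each cell's CPM 316 and 142. Of the 125 genes named over all cells or in lists, 112 kept their sign in every setting run, as did all 80 pairs of a gene and a class, although EARLI1 within root-cap-like cells had -0.12 under the stricter filter (main -4.60). The glucosinolate median ran from 1.74 to 2.17, root cap from 0.69 to 1.55, nitrate from 0.66 to 1.31 and xylem from -1.85 to -0.29. Of 28 list medians, 10 had the opposite sign in at least 1 setting, suberin in 9 of 11.

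A minimum of 1 CPM gave 754 higher and 602 lower genes and 50 CPM gave 163 and 71, since more or fewer genes were compared. Lists with at least 2 measured members and a median at least 1.5-fold lower, 3 in the main setting, were 0 at 50 CPM, where fewer members were measured, and 0 under equal weight per class. Equal weight also gave 111 lower genes and a median of 0.14 for mesophyll and photosynthesis.

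For class shares (log2 ratio), no centring gave -0.51 for quiescent-centre-like cells. Resolution 0.5 gave -0.10 for epidermis-like and 1.32 for root-cap-like cells, and resolution 1.2 gave 0.67 for epidermis-like cells. With 3000 genes and 50 components the values were -0.39 for quiescent-centre-like, 0.96 for epidermis-like, 1.29 for root-cap-like and 0.079 for cluster 8 cells. Leaving out cell cycle genes gave 0.93 for root-cap-like cells. Doublets kept in gave 0.19 for quiescent-centre-like, -0.26 for epidermis-like and 1.58 for root-cap-like cells. The stricter filter gave -0.47 for quiescent-centre-like, 0.14 for epidermis-like, -0.35 for cluster 7 and -0.39 for xylem-like cells. At least 3000 UMIs gave -0.46 for quiescent-centre-like, 0.74 for epidermis-like, 0.81 for root-cap-like, -0.10 for cluster 7 and -0.53 for xylem-like cells. Thinning before clustering gave -0.22 for quiescent-centre-like, 0.26 for epidermis-like and -0.20 for xylem-like cells. Thinning and the UMI minimum leave out, by construction, the 106 xylem-like cells of the 7-day library with under 2000 UMIs. Cluster 5 stayed between -1.69 and -1.20 and G2/M-like cells between -1.15 and -0.66.

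Within epidermis-like cells, no centring gave 197 higher and 190 lower genes, leaving out cell cycle genes 227 higher, and doublets kept in 228 and 199. Within quiescent-centre-like cells 3000 genes gave 181 and 79.

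For cell shares, no thinning gave -0.38 for S phase, 0.078 for PLT3 and 0.13 for PLT5. Thinning to 1000 UMIs gave 0.072 for S phase in quiescent-centre-like cells and -1.35 for G2 and M phase. G2 and M phase had -1.19 with 3 genes per cell and -1.29 with doublets kept in, where 4 regulators were at least 1.5-fold higher.

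Some classes had no counterpart: S-phase-like without centring, at resolution 0.5 and with doublets kept in; sieve-element-like without centring, at resolution 1.2, under the stricter filter, at 3000 UMIs and after thinning; cluster 7 at resolution 0.5 and with 3000 genes. Too few cells were left for levels within epidermis-like cells (3000 genes) and cluster 4 (3000 UMIs). Depth limits the rare regulators, since LBD17, LBD29, PUCHI and WOX12 were seen in at most 14 thinned cells per library.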

Other observations

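Aquaporins with at least 5 CPM in one library or the other were gathered as families after the named genes were seen. Family members below that level are not counted here. Of 12 plasma membrane (PIP) genes, 8 were at least 1.5-fold lower in the 12-day library, 1 was higher and 3 were in between, with a median log2 ratio of -0.75, PIP1C and PIP2A included. PIP2B stood at 140 and 50.9 CPM and PIP1;4 at 317 and 145 CPM, while PIP2;4 was higher (8.18 and 13.6 CPM). Of 4 tonoplast (TIP) genes, 3 were lower, with GAMMA-TIP at 578 and 323 CPM, DELTA-TIP at 542 and 300.2 CPM and a median of -0.85. The 4 NIP genes, a family that carries boric acid and other small solutes, had a median of 0.98, with NIP2;1 (3.69 and 19.1 CPM) and NIP5;1, for a boric acid channel, (99.5 and 269 CPM) higher. The 3 SIP genes had a median of 0.08. The PIP, TIP and NIP medians kept their sign under 4 alternative scalings (PIP from -0.90 to -0.47) and in all 8 classes compared. Scaling with organelle genes included or with size factors shifts all ratios by the same small constant, so it could not change these signs. BRX, which carries an aquaporin synonym of a neighbour in the reference, was left out.

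Classes differed from each other in the level of several lists within both libraries, by summed CPM. Ribosomal protein genes summed to 1148 and 1353 CPM in root-cap-like cells at 7 and 12 days, against 8604 and 8318 in quiescent-centre-like and 11457 and 9736 in G2/M-like cells. Heat shock genes summed to 5724 and 6315 CPM in cluster 8, hypoxia genes to 5877 and 4544 CPM in cluster 5, and pluripotency regulators to 744 and 735 CPM in cluster 1. Photosynthesis genes summed to 432 and 242 CPM in cluster 5 and to 177 and 254 CPM in cluster 8. In cluster 14, at 12 days, jasmonate genes summed to 9858 CPM, auxin response genes to 1666 CPM and pathogen defence genes to 256 CPM. Where a list is given for a single class, its sum is a level and not a comparison with other classes. Single genes of cluster 14, picked after their values were seen, were ZAT12 (3026 CPM), JAZ1 (1879 CPM), WRKY33 (1131 CPM), GH3.3 (573 CPM), PAD3 (127 CPM) and PR2 (123 CPM).

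Single organelle genes took much of the organelle UMIs. ATMG00020 held 84.8% of the mitochondrial UMIs of kept cells at 7 days and 85.2% at 12 days, and ATCG01130 15.1% and 12.6% of the plastid UMIs.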
